A study of Homo sapiens with 4 samples.

How the data were processed

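Total RNA of MCF7 cells, an estrogen receptor positive human breast cancer line, was measured on 4 two-colour Agilent arrays. On each array an RNA of the line with an inserted MYF6 gene (MYF6 Rec1) was hybridised against an RNA of the control line with the empty vector, and both lines had received doxycycline at 50 ng per ml for 48 h, per the labels' protocols. The labels call the arrays biological replicates 1 to 4 and place MYF6 Rec1 in Cy5 and the control in Cy3 on replicates 1 and 2, and the reverse on replicates 3 and 4. All 4 arrays lay on 1 slide and were scanned as 1 batch, so no slide or scan batch separated them.

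The scanner files hold spot intensities that Agilent Feature Extraction 10.7.3.1 wrote, per the file headers, as median pixel intensities of the spot and its local background in each channel. The same files hold background-subtracted, dye-normalized processed intensities and a log10 ratio of processed red (Cy5) over processed green (Cy3), per the file headers. The array design was annotated on hg19, per the file headers. The design chosen in advance named mean signals, but the files hold median signals, which were used in their place. The authors' value table gives 1 score per probe and array, made with limma in R 3.0.1 per the submitters' processing notes, with steps, scale and direction not given in the sources used here. Set against the scanner values, the authors' scores ran as green over red on replicates 1, 2 and 4 and as red over green on replicate 3. They were compressed, with a slope of 0.205 per log2 unit on replicate 1 for probes with a mean log2 intensity under 8 and of 0.104 for those over 12. The medians of the authors' columns were -0.0016, -0.002, -0.0009 and -0.0008 for replicates 1 to 4. The base of the scale and the condition in the numerator remain unknown. If the scores are MYF6 Rec1 over control, RNA Y defined below is MYF6 Rec1, as by the label of replicate 4, and if they are control over MYF6 Rec1, RNA X is. The table therefore served only as an alternative and for the orientation described below.

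The intensities were background-corrected with normexp (offset 50) on all spots and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0). Control spots and spots with a non-uniformity or population outlier flag were then left out, and the spots of each probe were averaged. Of 42405 probes, 28259 were tested because they lay well above background in the channel of a condition on at least 3 of the 4 arrays. No spot was saturated. The files pair probes with accessions and not with symbols. Accessions were matched without versions to RefSeq names of GRCh38.p14, a different build, from which only names and the order of neighbouring genes were used and no coordinate. This named 26364 probes and left 883 RefSeq accessions unmatched and 16041 probes unnamed in all. A gene was represented by its tested probe with the highest mean log2 intensity, which gave 14656 genes (probes are given by gene name, and MYF6 by its probe identifier). Of the 3622 genes with more than 1 tested probe, 2302 were called between RNA X and RNA Y (defined below), and over all called genes 99 had another probe called the opposite way.

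The fit planned before the data were examined coded MYF6 Rec1 over control by the labelled dyes, added a probe-specific dye term and used limma's lmFit and eBayes with Benjamini-Hochberg adjustment over all tested probes, with calls at an adjusted p under 0.05. A further fit was chosen after the arrays had been seen to run in opposite ways. In it, RNA X is the RNA in Cy5 on replicates 1, 2 and 4 and in Cy3 on replicate 3, and RNA Y is the other RNA of each array. This orientation was read from the sign of the authors' columns against the scanner ratios and not from any gene. X is MYF6 Rec1 and Y the control by the labels of replicates 1 to 3, and the reverse by the label of replicate 4. Differences are given as X minus Y on the log2 scale, with the moderated standard error (SE). Because replicate 3 is the only array with X in Cy3, the dye term gives it a weight of 50% in each fitted difference and the other arrays 16.7% each. Its deviation from the others does not enter the SE, which rests on the spread among replicates 1, 2 and 4 and on the variance pooled over probes. The dye term absorbs that deviation, whether it is a dye effect or an error of replicate 3. Values of X minus Y without replicate 3 have no dye term, so any dye effect stays in them. Because the normexp offset draws ratios of dim probes toward 0, their folds are understated.

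In the same design, 20 gene lists with 658 entries (651 matched to a name) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 20 lists. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays and not from the number of genes. It could therefore hardly call any list here, whatever the correlation, and a call lost in that setting does not by itself speak against a list. The estimated correlations ran from -0.108 (myogenic regulators) to 0.472 (hypoxia and glycolysis). Where the correlation within a list is above 0.01, camera's p at the preset correlation is too small. Genes were named by a fixed rule: MYF6, the 10 largest changes in each direction among called genes with the same sign on all 4 arrays and a probe well above background on all 4 arrays in the brighter RNA, up to 3 called members of each list with the smallest adjusted p, and 10 genes set in advance (MYOD1, MYF5, MYOG, ESR1, PGR, GREB1, TFF1, CDKN1A, MKI67 and CCND1). On the fit as labelled the first parts of the rule name 0 genes, so the rule was applied to X minus Y. No gene named from the fit was below background on every array of either RNA, so no fold had to be given as a bound. Other genes named for a list were chosen after their values were seen.

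On data simulated for RNA X against RNA Y with the residual spread of the fit and its dye terms (28226 probes), the fit recovered 50% of the genes changed by log2 0.25 and 100% of those changed by 0.5, 1 or 2, and 7.21% of 222 called probes were unchanged. The simulation gave every array the same random spread. It carried the deviation of replicate 3 only as a dye effect, which the fit removes, and not as an error of that array. It also changed far fewer genes than were called in the data, so these rates do not carry over to the data. With the orientation of 1 simulated array wrong, it recovered 0% at every size, while camera still called the 1 shifted list. The number of arrays limits the precision. The series also describes a line MYF6 Rec2, of which no array was analysed here. The alternatives changed the dye term, background correction, normalization, signal, filter, flags, probe summary, variance model, array weights and arrays used, and separate-channel fits were made after Aquantile scaling.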

Results

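Expression was compared on 4 two-colour arrays between MCF7 cells with an inserted MYF6 gene (MYF6 Rec1) and MCF7 cells with the empty vector. MCF7 is an epithelial breast cancer line that depends on the estrogen receptor, and MYF6 encodes a transcription factor of the myogenic basic helix-loop-helix (bHLH) family. The study asked how inserted MYF6 alters gene expression and phenotype in this type of breast cancer. Each array held an RNA of either line, and the labels describe 4 biological replicates with a dye swap. All arrays set a single MYF6 line against a single control line. A difference between these lines unrelated to MYF6 therefore cannot be told apart from an effect of MYF6, for any gene or list. The SEs and p-values speak of these lines only. Between 28067 and 32020 probes lay well above background in the red channel of an array and between 26795 and 27972 in the green channel, of 42405 probes.

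MYF6 itself could not be used to check the labels. The array carries 1 MYF6 probe (A_23_P76460), which was not well above background in any of the 8 channels. Its log2 ratio of MYF6 Rec1 over control, with the dyes as labelled, was -0.02 ± 0.056 (SD, n = 4), between -0.09 on replicate 1 and 0.03 on replicate 4. Where this probe lies relative to the inserted sequence is not given in the sources used here, so this value shows neither presence nor absence of the inserted transcript.

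The direction of the comparison was not settled by the arrays. Replicates 3 and 4 carry the same dye labels, yet their red over green log2 ratios had a correlation of -0.79 across all probes (genes are not independent replicates). Replicate 4 instead ran with replicates 1 and 2, which carry the opposite labels, at correlations of 0.88 and 0.89, and replicate 3 ran against them at -0.82 and -0.80. With the dyes as labelled, limma with Benjamini-Hochberg adjustment called 0 of 14656 genes over the 4 arrays. The lowest adjusted p was 0.786, and 170 genes had an unadjusted p under 0.05. The labels of replicates 1 to 3 alone gave 9678 called genes by limma, 4744 higher and 4934 lower in the RNA labelled MYF6 Rec1. In that fit of 3 arrays the SE rests on replicates 1 and 2 and on the variance pooled over probes, so its count is no stronger evidence than one from 4 arrays. Without replicate 3, the labelled fit sets replicates 1 and 2 against replicate 4 alone. These arrays ran the same way, so that fit compares arrays and not the lines, and its calls are no measure of MYF6. In the same labelled fit over 4 arrays, camera called 5 of 20 gene lists, of which 0 were called with an estimated correlation, 0 by fry and 0 by camera without replicate 3. Further values are therefore given between RNA X (in Cy5 on replicates 1, 2 and 4 and in Cy3 on replicate 3) and RNA Y (the other RNA of each array), an orientation taken from the authors' value table after the data were seen. RNA X is MYF6 Rec1 and RNA Y the control by the labels of replicates 1 to 3. By the label of replicate 4 RNA X is the control and RNA Y is MYF6 Rec1, and every sign given for MYF6 Rec1 is turned.

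**Figure D1:**
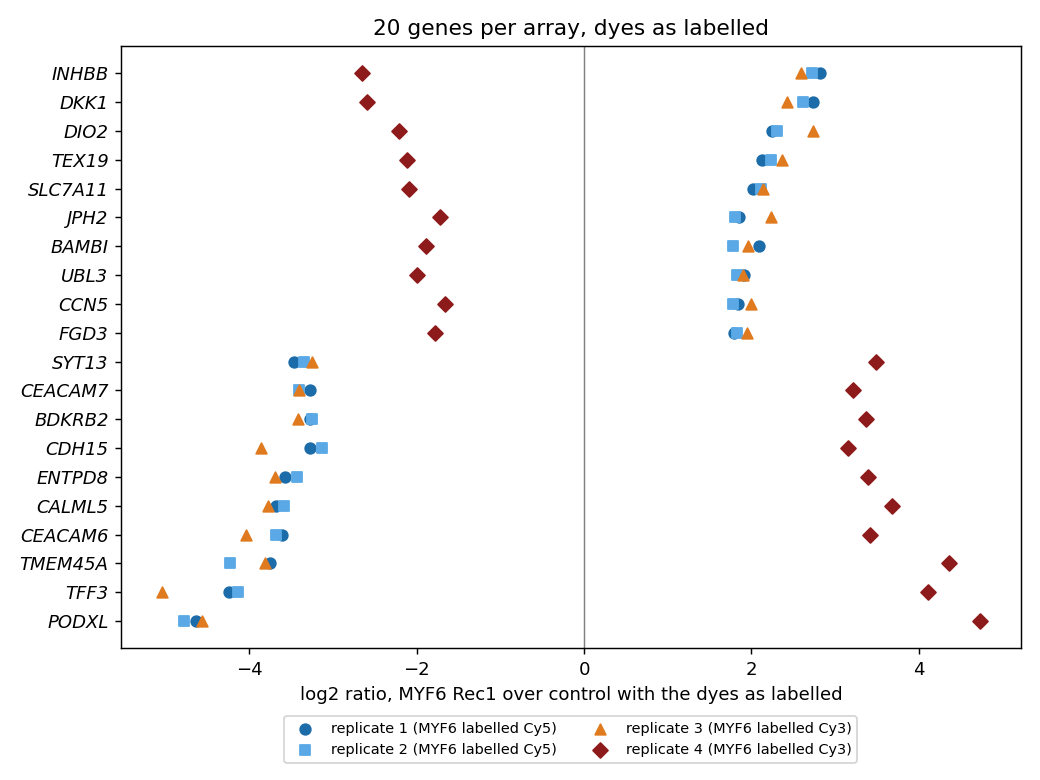
Log2 ratio of MYF6 Rec1 over control with the dyes as labelled (x axis) on each of the 4 arrays for the 10 genes highest in RNA X and the 10 highest in RNA Y (y axis), 1 point per array. The genes were chosen among those with the same sign of X minus Y on all 4 arrays, which by construction puts replicates 1, 2 and 3 on one side of 0 and replicate 4 on the other, so the plot shows sizes only.

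Among the genes that differed most, higher in RNA Y were PODXL, a sialomucin of the cell surface (24.9-fold, log2 difference X minus Y -4.64 ± 0.049, SE, n = 4 arrays), TFF3, a secreted trefoil peptide induced by estrogen (24.3-fold, -4.60 ± 0.049), and TMEM45A (15.5-fold, -3.96 ± 0.093). The adhesion glycoproteins CEACAM6 and CEACAM7 were 13.9-fold and 10.2-fold higher in Y, and CDH15, the M-cadherin of muscle cells, was 11.5-fold higher. These SEs leave out the deviation of replicate 3 (the SD of TFF3 over the 4 arrays was 0.44). Without that array, TFF3 was 17.9-fold and CDH15 9.09-fold higher in Y, while PODXL was 26.3-fold and TMEM45A 17.3-fold higher. No dye term can be fitted without it, so these folds hold any dye effect and are not the more reliable ones. The calmodulin-like CALML5, the nucleotidase ENTPD8, the bradykinin receptor gene BDKRB2 and SYT13 were between 10.1-fold and 13.1-fold higher in Y. Higher in RNA X were INHBB, a subunit of activin and inhibin (6.33-fold, 2.66 ± 0.050), the secreted Wnt inhibitor DKK1 (5.81-fold, 2.54 ± 0.049) and the deiodinase DIO2 (5.63-fold, 2.49 ± 0.047). TEX19, the cystine transporter SLC7A11, JPH2, the TGF-beta pseudoreceptor BAMBI, UBL3, CCN5 and FGD3 were between 3.67-fold and 4.80-fold higher in X. These 20 genes were chosen among those with the same sign of X minus Y on all 4 arrays, and their adjusted p by limma lay between 1.60e-12 and 1.91e-09.

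Over all genes, limma called 8660 of 14656 (59.1%) between RNA X and RNA Y, 4233 higher in X and 4427 higher in Y. By the labels of replicates 1 to 3, the 4233 genes are higher and the 4427 lower in MYF6 Rec1, and the label of replicate 4 turns this round. Of the called genes, 430 differed at least 2-fold, 116 higher in X and 314 higher in Y, and all 430 had the same sign on all 4 arrays, as had 7944 of the 8660. Replicate 3 carries a weight of 50% in these fitted values and does not enter their SE. Without it, and so without a dye term, 7514 of the 8660 were called with the same sign and 173 had the opposite sign. At least 4-fold differences numbered 6 in X and 62 in Y. Median centring in place of loess put 63.4% of called genes higher in X against 48.9% with loess, and the number of 2-fold genes rose to 790 with a normexp offset of 0 and to 1005 with Agilent's processed signals.

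Genes of cell division were mostly higher in RNA X. Of 39 tested mitosis genes, 39 were higher in X, with a median log2 difference of 0.72, and 39 were called when adjusted over the list alone. PRC1, which bundles spindle microtubules, was 2.11-fold higher in X (1.08 ± 0.046), the transcription factor FOXM1 2.04-fold (1.03 ± 0.048), the mitotic cyclin CCNB1 2.00-fold (1.00 ± 0.047) and the proliferation marker MKI67 1.65-fold (0.72 ± 0.061). Of 35 DNA replication genes, 30 were higher in X and 3 in Y, with a median of 0.42 and 33 called when adjusted over the list alone. They included the thymidylate synthase gene TYMS (1.88-fold, 0.91 ± 0.045), RFC3 (1.74-fold) and POLE2 (1.66-fold). Camera gave an adjusted p of 1.01e-17 for mitosis and of 5.88e-08 for DNA replication, and for each the adjusted p = 0.394 with an estimated correlation. By the labels of replicates 1 to 3 the genes of both lists that were higher in X were higher in MYF6 Rec1, and by the label of replicate 4 they were lower. The 3 DNA replication genes higher in Y went the other way. Cell cycle arrest genes went both ways, with 14 of 32 p53 targets and arrest genes higher in X and 9 in Y, 23 called when adjusted over the list alone, and a camera adjusted p of 0.505. GADD45G was 2.42-fold, TP53INP1 1.98-fold, PLK2 1.77-fold and the CDK inhibitor CDKN1A 1.26-fold (-0.33 ± 0.055) higher in Y, as was the G1 cyclin CCND1 (1.23-fold, -0.30 ± 0.053), which was not called with median centring (adjusted p 0.0812 by limma).

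Hypoxia and glycolysis genes were higher in RNA Y. All 29 tested members were higher in Y, 11 of them at least 2-fold, with a median X minus Y of -0.83, and 29 were called when adjusted over the list alone. ADM, the vasodilator adrenomedullin, was 5.63-fold higher in Y (-2.49 ± 0.079), the collagen prolyl hydroxylase P4HA2 2.96-fold (-1.57 ± 0.057) and the glycolytic regulator PFKFB4 2.97-fold (-1.57 ± 0.061). Camera gave an adjusted p of 1.93e-12 for this list, and the adjusted p = 0.631 with an estimated correlation. That estimate was 0.47, against the preset 0.01. If it holds, camera's p at the preset correlation is far too small for this list. Interferon response genes were also more often higher in Y, 23 of 36 against 5 higher in X (21 against 3 without replicate 2, 20 against 1 with a normexp offset of 0 and 21 against 8 with median centring), with a median of -0.32 and 29 called when adjusted over the list alone. IFIT1 was 3.25-fold higher in Y (-1.70 ± 0.058), IFI6 3.23-fold and the transcription factor IRF7 2.98-fold. The camera adjusted p was 0.000324 for interferon response, and the adjusted p = 0.540 with an estimated correlation. The genes of both lists that were higher in Y were lower in MYF6 Rec1 by the labels of replicates 1 to 3 and higher by the label of replicate 4. The 5 interferon genes higher in X went the other way.

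**Figure D2:**
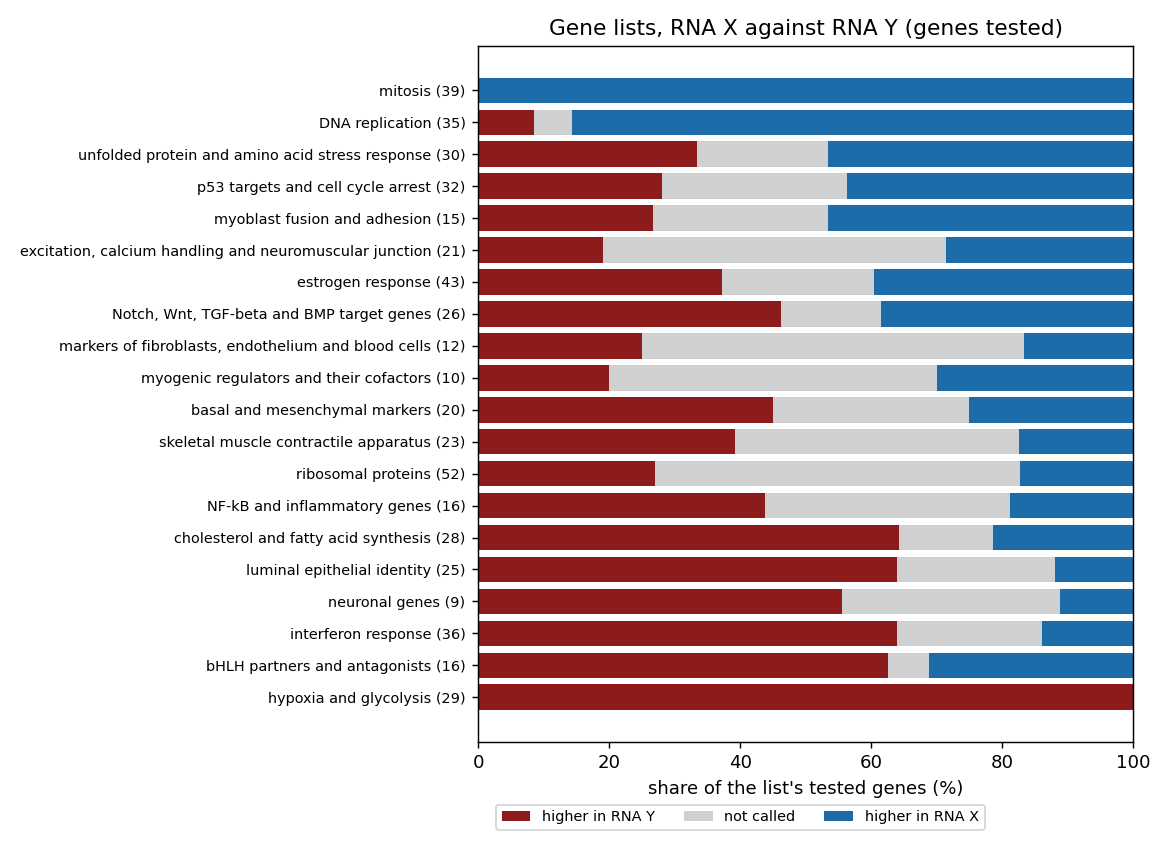
Share of the tested genes of each of the 20 fixed lists (y axis, with the number tested) that limma called higher in RNA Y, did not call, or called higher in RNA X (x axis, percent). Mitosis (39 of 39 higher in X) and hypoxia and glycolysis (29 of 29 higher in Y) are the lists in which every tested gene went the same way.

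Epithelial genes shifted mostly toward RNA Y. Of 25 luminal identity genes, 16 were higher in Y and 3 in X (11 and 5 with median centring), with a median of -0.21 and 19 called when adjusted over the list alone. The mucin MUC1 was 4.48-fold higher in Y (-2.16 ± 0.045) and CD24 2.83-fold, whereas AGR2 was 2.85-fold higher in X (1.51 ± 0.046). The camera adjusted p was 0.00358 for luminal identity, and the adjusted p = 0.440 with an estimated correlation. Among 20 basal and mesenchymal markers, 5 were higher in X and 9 in Y, 14 were called when adjusted over the list alone, and the camera adjusted p was 0.306, against 0.0415 with median centring and 0.0364 to 0.890 over all alternatives. CAV1 was 3.21-fold and TGFBI 2.56-fold higher in X, and S100A4 was 5.64-fold higher in Y. By the labels of replicates 1 to 3, RNA Y is the control, and by the label of replicate 4 it is MYF6 Rec1.

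Estrogen-regulated genes did not move together. Of 43 tested genes, 17 were higher in RNA X and 16 in RNA Y, with a median of 0.00, a mean of -0.09, 35 called when adjusted over the list alone and a camera adjusted p of 0.800. TFF3 and the protease inhibitor SERPINA1 (4.60-fold) were higher in Y and CCN5 was 3.68-fold higher in X. The estrogen receptor gene ESR1 was 1.23-fold higher in X (0.29 ± 0.047), while its targets GREB1 (1.66-fold, -0.73 ± 0.050) and TFF1 (2.05-fold, -1.04 ± 0.050) were higher in Y. TFF1 was at -1.73 on replicate 3 and between -0.43 and -0.25 on the other arrays (SD 0.69, n = 4), so that its SE of 0.050 leaves out this spread. Without replicate 3, and so without a dye term, it was 1.28-fold higher in Y (-0.35). Which of these sizes is nearer the truth cannot be told, since a dye effect and an error of replicate 3 look alike here. PGR, the progesterone receptor gene, was not called (-0.12 ± 0.047, limma adjusted p 0.0629), but 12 of 19 alternative settings called it higher in Y (adjusted p from 0.00467). Its probe was well above background on 1 of 4 arrays in X and 3 of 4 in Y, and could not be tested with the stricter filter. Its value moved to -0.51 with a normexp offset of 0 and to -1.02 with Agilent's processed signals, so its size is uncertain. Camera and fry differed in sign for this list, since fry gave Y as the higher RNA with an adjusted p of 0.0427 (0.0427 to 0.988 over all alternatives). With the sign turned, X is the control and Y is MYF6 Rec1.

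Several muscle genes were higher in RNA Y, while the muscle list was not called. Over all tested genes 59.1% were called, so a count of called members does not by itself set a muscle list apart. Of 23 tested genes of the skeletal muscle contractile apparatus, 9 were higher in RNA Y and 4 in RNA X (8 and 2 without replicate 3), with a median of -0.06 and 13 called when adjusted over the list alone. The fast troponin TNNI2 was 3.15-fold higher in Y (-1.65 ± 0.046), the muscle enolase ENO3 2.46-fold (-1.30 ± 0.046) and myoglobin (MB) 1.88-fold (-0.91 ± 0.049). The camera adjusted p for this list was 0.245, against 0.0290 with median centring and 0.00542 by fry (0.00542 to 0.686 over all alternatives). Of 21 genes of excitation, calcium handling and the neuromuscular junction, 6 were higher in X and 4 in Y (1 and 3 with the stricter filter on dim probes), 9 were called when adjusted over the list alone, and the camera adjusted p was 0.630. JPH2, a junction protein of muscle membranes, was 4.04-fold higher in X. CACNG1 was higher in X (0.53) and the acetylcholine receptor subunit gene CHRNA1 higher in Y (-0.79), each against an RNA in which its probe was well above background on 1 of 4 arrays, and neither could be tested with the stricter filter. The myogenic regulators MYOD1 (-0.04 ± 0.046) and MYOG (-0.02 ± 0.048) were not called, with limma adjusted p of 0.554 and 0.713, and MYF5 was not well above background on any array. Of 10 tested myogenic regulators and cofactors, 3 were higher in X and 2 in Y, 5 were called when adjusted over the list alone, and the camera adjusted p was 0.743. MEF2D was 2.17-fold and SIX1 1.18-fold higher in Y (SIX1 was not called with median centring, limma adjusted p 0.344), and MEF2A was 1.16-fold higher in X. Among 15 genes of myoblast fusion and adhesion, 7 were higher in X and 4 in Y, 12 were called when adjusted over the list alone, and the camera adjusted p was 0.722. CDH15 and CD9 (1.69-fold) were higher in Y and ADGRB1 was 1.74-fold higher in X (1.39-fold without replicate 3). For this list the median was 0.03 and the mean -0.16, and fry gave Y as the higher RNA (adjusted p 0.0108, with 0.0108 to 0.901 over all alternatives). RNA Y is the control by the labels of replicates 1 to 3 and MYF6 Rec1 by the label of replicate 4.

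In the list of bHLH partners and antagonists, 10 of 16 genes were higher in RNA Y and 5 in RNA X, with a median of -0.41 and 15 called when adjusted over the list alone. HEY1, a Notch target, was 4.34-fold higher in Y (-2.12 ± 0.064), ID2, an inhibitor of bHLH factors, 2.91-fold (-1.54 ± 0.045) and HES6 2.11-fold. The tested E protein genes, which encode dimerization partners of myogenic bHLH factors, were instead higher in X, TCF3 1.52-fold (0.60 ± 0.046) and TCF12 1.19-fold (0.26 ± 0.053). TCF12 lies in a run of 41 neighbouring genes (NDUFAF4P1 to MYZAP, described below), of which 33 were higher in X with a median of 0.52. Its difference may thus belong to the run and not to the E proteins. The camera adjusted p of the list was 0.0401, the adjusted p = 0.678 with an estimated correlation, and it was 0.625 when genes in other lists were left out, 0.0552 with a normexp offset of 0 and 0.0764 on the authors' value table (3.47e-05 to 0.678 over all alternatives). Of 26 target genes of Notch, Wnt, TGF-beta and BMP signalling, 10 were higher in X and 12 in Y, 22 were called when adjusted over the list alone, and the camera adjusted p was 0.743. DKK1, HEY1 and ID2 were the members with the smallest adjusted p. The sign for MYF6 Rec1 is negative for these Y-higher genes by the labels of replicates 1 to 3 and positive by the label of replicate 4.

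**Figure D3:**
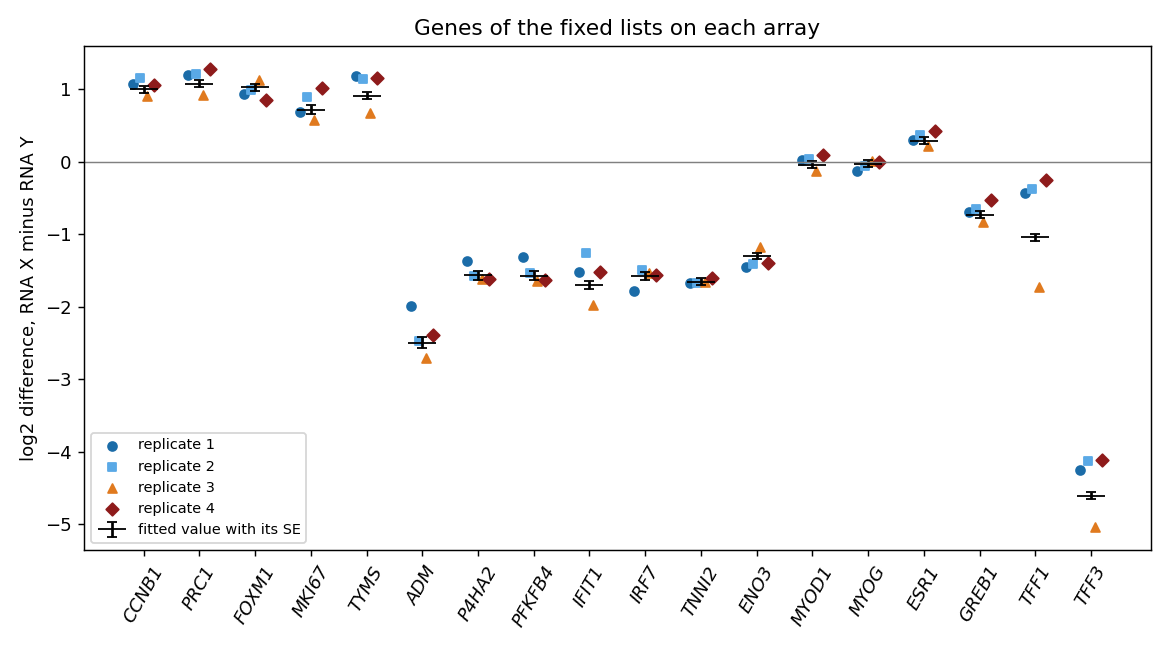
Log2 difference of RNA X minus RNA Y (y axis) for 18 genes of the lists and the set named in advance (x axis), with 1 point per array (n = 4) and the fitted value with its SE in black. Cell division genes lie above 0 and hypoxia, interferon and troponin genes below 0 on every array, MYOD1 and MYOG lie near 0, and TFF1 and TFF3 are lowest on replicate 3.

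Metabolic and stress lists were divided. Of 30 genes of the unfolded protein and amino acid response, 14 were higher in RNA X and 10 in RNA Y, 25 were called when adjusted over the list alone, and the camera adjusted p was 0.245, against 0.0246 without replicate 1 and 0.00404 with median centring (0.00404 to 0.773 over all alternatives). SLC7A11 (4.31-fold) and the serine synthesis enzyme PSAT1 (3.16-fold) were higher in X, and the chaperone DNAJB9 was 1.81-fold higher in Y. Of 28 genes of cholesterol and fatty acid synthesis, 18 were higher in Y and 6 in X (9 and 6 with median centring, 11 and 4 on the authors' value table), 24 were called when adjusted over the list alone, and the camera adjusted p was 0.0629, against 0.0484 without replicate 3 and 0.0318 with no filter on dim probes (0.0149 to 0.678 over all alternatives). ELOVL6 was 2.15-fold higher in X, and SREBF1 (1.90-fold) and the LDL receptor gene LDLR (1.52-fold) were higher in Y. NF-kB and inflammatory genes comprised 3 of 16 higher in X and 7 in Y (1 and 7 without replicate 2, 1 and 8 without replicate 3, 4 and 5 with median centring), with 10 called when adjusted over the list alone and a camera adjusted p of 0.419. LIF was 1.80-fold and ZC3H12A 1.35-fold higher in Y and NFKBIA 1.54-fold higher in X. Ribosomal protein genes had no direction that held over the settings, with 9 of 52 higher in X and 14 in Y, 20 called when adjusted over the list alone and a camera adjusted p of 0.625. The split was 16 in X and 0 in Y with median centring, 9 and 0 with Agilent's processed signals, 10 and 0 on the authors' value table, 10 and 3 with no dye term, 6 and 9 without replicate 2 and 29 and 6 without replicate 3. RPL12 was 1.43-fold higher in X (1.87-fold without replicate 3). RPS27 and RPL34 had fitted values of -0.26 and -0.25, but both were higher in X on 3 of the 4 arrays and neither was called with no dye term, median centring, processed signals or the authors' value table. Without replicate 3, which removes the dye term, the ribosomal list was called higher in X (adjusted p 0.00202, with 0.00202 to 0.976 over all alternatives), and RPS27 and RPL34 changed sign. By the label of replicate 4 these signs are turned for MYF6 Rec1.

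Markers of other cell types were few on these arrays. Of 30 markers of fibroblasts, endothelium and blood cells, 12 were tested, 2 were higher in RNA X and 3 in RNA Y (1 and 3 without replicate 1, 1 and 2 without replicate 3), 5 were called when adjusted over the list alone, and the camera adjusted p was 0.743. CD68 was 1.58-fold and HBG1 1.19-fold higher in Y, and CD19 was 1.18-fold higher in X (1.33-fold without replicate 3). Of 9 tested neuronal genes, 5 were higher in Y and 1 in X, 6 were called when adjusted over the list alone, and the camera adjusted p was 0.245. The proneural factor ASCL1 was 2.36-fold and TUBB3 1.45-fold higher in Y, and L1CAM was 1.64-fold higher in X. Across the 20 lists, camera called 6 between X and Y, 0 were called with an estimated correlation, and fry, which does not compare a list with other genes, called 17. The reading of X and Y as MYF6 Rec1 and control stays open here too, and with the sign turned Y takes the place of X.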

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

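The values in this part are X minus Y, an orientation chosen after the data were seen, and the outlier measure itself was set beforehand. Among 108 sets of 4 array values (named genes, list medians and array measures), 16 had an array far from the others relative to the range of the set. Chance gives this in about 1 of 20 sets if the arrays differ by random error alone. Replicate 3, the only array with RNA X in Cy3, was the outlying array in 15 of the 16. These values are not corrected for dye, so a probe-specific dye effect alone would set replicate 3 apart. The rate of 1 in 20 therefore does not apply to it, and a dye effect cannot be told apart from an error of that array.

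TFF3 stood at -5.04 on replicate 3 and between -4.25 and -4.11 on the others (X minus Y, log2). TFF1 stood at -1.73 against -0.43 to -0.25, ID2 at -1.68 against -1.42 to -1.38, MUC1 at -2.22 against -2.12 to -2.11, and LIF at -0.95 against -0.77 to -0.74. CAV1 was at 1.95 on replicate 3 against 1.38 to 1.47, and ADGRB1 at 1.13 against 0.45 to 0.50. TYMS was at 0.67 against 1.14 to 1.18, CD19 at 0.061 against 0.38 to 0.43, and LDLR at -0.45 against -0.78 to -0.73. RPL12 was at 0.13 against 0.88 to 0.92, RPS27 at -0.58 against 0.030 to 0.11, and RPL34 at -0.68 against 0.16 to 0.21. The median of the ribosomal protein list was -0.25 on replicate 3 against 0.13 to 0.15, and that of the myogenic regulators was -0.058 against 0.00089 to 0.0066. ELOVL6 was at 1.20 on replicate 4 and between 1.08 and 1.10 on the others.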

How the results depend on the processing

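The comparison of X with Y itself, and the settings that turn replicate 4, use the labelled dyes for X and Y, leave out replicate 3 with the dye term, or keep replicates 1 and 2 alone, and the counts on the weight of replicate 3, were chosen after the data were seen. As labelled, the gene count stayed at 0 in all settings except those without replicate 3 or replicate 4 (0 to 9678 with a replicate left out) and with replicate 4 turned (8660). The 5 lists called as labelled were 3 with Agilent's processed signals and with the authors' table, 0 with an estimated correlation and by fry, and 0 to 6 with a replicate left out. MYF6 (-0.02) was at -0.17 with normexp offset 0 and at 0.19 with processed signals, from a probe at background. The filter, variance model, weights and probe average do not enter this mean of 1 probe, and its dye term and separate-channel fit were not run. Between X and Y, settings at an adjusted p under 0.05 that kept the orientation gave 7255 to 9678 genes (7924 to 9678 with a replicate left out), an adjusted p under 0.01 gave 6983, and the labelled dyes gave 0. Genes at 2-fold numbered 790 with normexp offset 0, 1005 with processed signals and 0 with the labelled dyes, against 430, and no such count was made from the authors' table, whose scale is unknown. Of the 8660 genes, 7772 were called with the same sign with no dye term and 7514 without replicate 3. Calls higher in X were 63.4% with median centring and 48.9% with loess. The 6 lists became 0 with an estimated correlation, a setting that could hardly call a list on 4 arrays, and 17 by fry. The mitosis list had an adjusted p of 0.394 with an estimated correlation, and the muscle contractile list of 0.0290 with median centring and 0.00542 by fry. Fry put the estrogen response (0.0427) and myoblast fusion (0.0108) higher in Y, against uncalled shifts to X by camera. The ribosomal list was called higher in X without replicate 3 (0.00202) and with replicates 1 and 2 alone (0.00567), where RPS27 stood at 0.056 and 0.031 and RPL34 at 0.18 and 0.19. Neither setting can hold a dye term, and the cause of these and the other changes was not tested. Over 81 named genes and their alternatives, 1513 values stayed on their side of the threshold, 88 lost a call (78 with the labelled dyes), 12 gained one (all PGR) and 4 turned (RPS27 and RPL34). The uncalled MYOD1 also changed sign, in 4 settings. Mitosis had 39 of 39 genes higher in X, and hypoxia and glycolysis 26 to 29 genes higher in Y, in every setting but the labelled dyes. List tests were not run on separate channels. Signal over background left 23 of 51 muscle contractile genes and 12 of 30 markers of other cell types to be tested.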

Other observations

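The gene families and the genes named in this part, the tests on the orientation of the arrays, the windows of neighbouring genes, the correlations of genes 1 apart and the sign patterns for X and Y were chosen after the results were seen. Metallothioneins, small metal-binding proteins, were higher in RNA X for 7 of 9 tested genes and higher in Y for 0 (7 to 8 in X over 5 scalings), with MT2A 2.92-fold and MT1E 2.65-fold higher. S100A genes, which encode calcium-binding proteins, were higher in Y for 12 of 13 (9 to 12 over the scalings), with S100A4 5.64-fold and S100A6 4.41-fold higher. CEACAM adhesion genes were higher in Y for 8 of 8 (6 to 8 over the scalings), and keratins for 13 of 30 against 1 higher in X (12 to 13 against 1 to 4), with KRT16 5.24-fold and KRT15 3.40-fold higher in Y. KRT18 and KRT32 were called higher in Y although only replicate 3 was negative (-0.71 and -0.58). KRT80 and S100A14, also called higher in Y, were positive on replicate 3 alone (0.026 and 0.17). Each scaling keeps the weight of replicate 3, so the ranges do not show this dependence. Camera adjusted p over these 4 families lay between 7.67e-06 and 0.00668, and between 0.194 and 0.211 with an estimated correlation. Since the families were chosen after their values were seen, these p-values describe them and do not test them. Hybridisation between related copies within a family was not tested. X is MYF6 Rec1 by the labels of replicates 1 to 3 and control by that of replicate 4. Among 9050 tested probes without a gene name, 2665 were called and 59 differed at least 2-fold, including 959 called and 15 at 2-fold among 4101 probes of long intergenic RNAs.

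Replicates 3 and 4 share dye labels and run opposite ways. A dye bias keeps its sign on every array, which the lowest correlation between arrays (-0.82) argues against, and spike-in RNAs, with a lowest correlation of 0.999 between arrays, argue against red and green exchanged within a file. A wrong dye label on 1 array is a candidate explanation, since turning replicate 4 alone brought the lowest correlation between arrays to 0.79, and turning replicate 1, 2 or 3 alone left it at -0.93, -0.93 and -0.89. Whether the label of replicate 4 or those of replicates 1 to 3 are wrong cannot be told apart, since the MYF6 probe was well above background in 0 channels. No biological explanation was tested.

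The 4 arrays allow 7 sign patterns beside a dye term, too few for a share under 0.05. As labelled, limma called 0 genes (170 at an unadjusted p under 0.05), a count that all 7 patterns reach by construction. The highest other pattern, that of X and Y, gave 8660, and since it was chosen because the arrays run together in it, this restates their correlations and is no separate evidence. For the lists as labelled, 4 of 7 patterns gave at least the 5 of the labelled pattern, with 6 as the highest other. Between X and Y, 1 of 7 patterns, the chosen one of X and Y itself, reached 8660 genes and 430 genes at 2-fold, and the highest other gave 0 for both. For the lists between X and Y, 2 of 7 patterns reached the 6 of that chosen pattern, with 6 as the highest other.

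Mitosis genes were higher in RNA X and hypoxia genes higher in RNA Y. A brightness-dependent bias left by the normalization was tested with 10000 random lists matched on brightness. Their medians lay between -0.24 and 0.27 for mitosis and between -0.32 and 0.29 for hypoxia, against real medians of 0.72 and -0.83, and 0 of them were as high or as low, which argues against such a bias as the cause. An effect of MYF6, a difference between the lines unrelated to MYF6 and a difference in growth or oxygen between the cultures remain open and untested.

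Neighbouring genes tended to differ the same way, with a correlation of X minus Y of 0.13 between adjacent tested genes (across genes, which are not independent replicates). For genes 20 apart, the distance set in advance, it was 0.030 against at most 0.029 in 1000 random orders, between the bounds set for copy number differences over long runs, which it therefore left open. Copy number differences limited to a few runs are a candidate explanation, since the highest median over 41 neighbouring genes was 0.52 (from NDUFAF4P1 to MYZAP), and 200 random orders stayed between -0.27 and 0.26. In that run 33 genes were higher in X, among them DTWD1 (1.37) and ARPP19 (1.28), and 2 in Y, and of 13715 overlapping windows over all chromosomes 138 lay above and 96 below every random order, on 8 chromosomes whose most extreme window was higher in X for 4 (0.26 to 0.52) and in Y for 4 (-0.33 to -0.28). Random orders also break shared regional regulation, which stays open, and no DNA measurement was analysed here.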
